A study of Mus musculus with 15 samples.

How the data were processed

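Single plasmacytoid dendritic cells (pDCs), the cell type that makes most type I interferon early in many viral infections, were sorted by flow cytometry from the spleens of mice carrying a yellow fluorescent protein (YFP) reporter behind Ifnb1, after infection with murine cytomegalovirus (MCMV). Per the labels' protocols, the cells were sorted into plates and sequenced by FB5P-seq, a plate method that reads the 5' end of each transcript and tags it with a well barcode and a unique molecular identifier (UMI) of 5 bases. The series holds 15 plates from 4 mice, 1 mouse for each of 0, 33, 36 and 48 h, and 4 sort gates. The gates were total pDCs, pDCs low or negative for surface LIFR (the leukaemia inhibitory factor receptor), the YFP-positive part of the LIFRlo/neg pDCs, and, at 33 h only, LIFR+ YFP+ pDCs.

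The deposited table holds raw UMI counts for 19680 genes in 1258 cells. Per the submitters' processing notes, bcl2fastq, STAR 2.5.3a and HTSeq 0.9.1 were used with the genome build GRCm38, and the order and settings of these steps are not given in the sources used here. The counts were used as deposited, with no rounding or rescaling. A deposited cell table gives each cell's plate, gate, ERCC spike-in count and index-sort fluorescence intensity, per the file headers. Whether the ERCC counts are reads or UMIs is not stated there. All 1258 cells were matched to a plate by the number in its title, and the gates of all 1258 cells equalled those of the labels. The wells behind cells that are not in the table, and any filter the authors applied to cells, were not analysed here.

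A UMI of 5 bases can take 1024 values, so a count per gene and cell cannot exceed 1024, and 22 values reached it. The median nonzero value was 59 UMIs and 14.1% of nonzero values were 1 UMI. Because low values were common beside very high ones, cells with at least 10 UMIs of a gene were counted as carrying its transcript in most shares. That limit was chosen after the values were seen, and shares at 1 UMI were the choice made before the data were examined. A short UMI and the splitting of reads among near-identical genes limit single values, so the split of reads among Ifna paralogs is uncertain and the gene Gm13281 of the same family is named with the same reserve. Strand handling in the counting is not given in the sources used here.

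The mouse was taken as the replicate, since cells and plates of 1 mouse are not independent. UMI counts were summed per mouse and gate, giving 1000473 to 70038069 UMIs per sum. For gate comparisons, 9 sums from the 3 infected mice entered 1 edgeR quasi-likelihood fit with the mouse as a block. The pairing comes from the animals: the gates of a time point were sorted from the same mouse. Total and YFP+ cells of a mouse also shared a plate, whereas LIFRlo/neg cells lay on plates of their own. Infected and uninfected total pDCs were compared as 3 mice against 1, with the lone uninfected mouse assumed to vary as the infected mice do. Genes were filtered with filterByExpr, libraries scaled by TMM, and p adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors (SE) were derived from the fold change and the quasi-likelihood F statistic and are approximate. Standard deviations (SD) are over mice. Fitted log2 fold changes of genes near 0 on one side depend on the prior count, so per-mouse log2 ratios use CPM (UMIs of a gene scaled to a common total of 1e+06 UMIs) with a pseudocount of 20 CPM, and such genes are described by cells.

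A further comparison was added after the cell table was seen. Within the LIFRlo/neg gate, cells were taken as YFP-negative up to the highest YFP intensity of any uninfected cell, 21.2, and as YFP-positive from 70.7 upwards, the lowest intensity of a sorted YFP+ cell, which left out 68 cells between these limits. It compared 152, 48 and 45 YFP-positive with 471, 104 and 33 YFP-negative cells at 33, 36 and 48 h, as sums paired by mouse.

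The time course of total pDCs and the comparison of LIFR+ YFP+ with LIFRlo/neg YFP+ cells at 33 h rest on 1 mouse per side. They are given as CPM with exact 95% Poisson intervals, log2 ratios and list medians with their percentile among 10000 random lists matched on expression, without any test. Shares of cells have exact 95% binomial (Clopper-Pearson) intervals, and a share of 0 is given with the share that 3 cells would make. Such intervals cover counting error only. Differences of shares between gates were tested by a two-sided exact sign-flip permutation test over 3 mice, whose smallest possible p is 0.25. For comparison at an equal number of UMIs each cell was thinned to 4000 UMIs, which left out 0 cells.

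Before the data were examined, 26 gene lists were fixed: type I and III interferon genes, interferon-stimulated genes, interferon-gamma-inducible genes, pDC identity, endosomal nucleic acid sensing, DC maturation, MHC class II and class I presentation, other cytokines and chemokines, NF-kappa-B targets, the unfolded protein response, cDC-associated and transitional DC-associated genes, cell cycle, glycolysis, cytosolic ribosomal proteins, mitochondrially encoded genes, dissociation stress, cell death, and markers of B cells, plasma cells, T cells, NK cells, neutrophils, monocytes and macrophages, and erythroid cells and platelets. Lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, repeated with an estimated correlation and with fry. Counts of members are given over all genes and adjusted over the list alone. Some lists share members, so they are not separate evidence. Relb and Cd83 are in the DC maturation and NF-kappa-B lists. Irf7 is in the interferon-stimulated and nucleic acid sensing lists, and Ctsl in the pDC identity and nucleic acid sensing lists. Camera compares a list with the other genes, so its direction can differ from the sign of a median when all genes shift. The median log2 fold change of all tested genes was -0.04 for infection, -1.44 for YFP+ against total, 0.25 for LIFRlo/neg against total, -2.16 for YFP+ against LIFRlo/neg and -0.33 for YFP-positive against YFP-negative cells. Scaling by summed UMIs alone moved these to -0.16, -1.28, 0.15, -1.90 and -0.54, scaling by RLE size factors to -0.02, -1.32, 0.13, -1.90 and -0.28, and scaling by ERCC totals to -0.01, -1.28, -0.09, -1.64 and -0.63. On leaving out 1 infected mouse they ranged more widely, from -0.23 to -0.06, -1.63 to -0.86, 0.19 to 0.46, -2.92 to -1.17 and -0.48 to -0.12.

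Genes are named by a rule set before the data were examined: Ifnb1 and Lifr in every comparison as a check of the gates, up to 10 called genes with the largest fold change in each direction that moved the same way in every mouse and had at least 30 UMIs on the higher side, and the 2 members with the smallest p of each list described. With 1 mouse per side it took the 10 largest log2 ratios in each direction. Yfp, Siglech, Ccr7, Ifnl2, Ifnl3 and a few others outside the rule were chosen after their values were seen, and are named as such where they first carry a statement.

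The fit was tested on simulated data, with 200 genes changed by known folds among the real genes. For infection over 12011 genes, 38.5% of the more abundant genes changed 16-fold and 4.2% of those changed 4-fold were recovered, and 36 of 64 calls were false. For YFP+ against total over 9979 genes, 36% and 8% were recovered with 3 false among 27 calls, and for YFP-positive against YFP-negative over 9215 genes 41.7% and 15.4% with 6 false among 40. Recovery among the less abundant genes was 8.3%, 4% and 11.5% at 16-fold and 3.8%, 0% and 0% at 4-fold.

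Alternatives were other scalings, DESeq2, limma-voom, no filter, other limits on cells, counts of cells in place of UMIs, correction for UMI collisions, fits without the mouse block and leaving out each infected mouse in turn. No deposited annotation of cell classes was at hand, so shares of the authors' classes were not analysed here. Cells were clustered instead with scanpy (2000 variable genes, 30 components, 15 neighbours, resolution 0.5) as a description. Doublets were not called, since each well was sorted with 1 cell by design, and the table held 0 duplicated cells. Positions are from the GENCODE annotation of GRCm38. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scanpy 1.11.5 and matplotlib 3.10.9.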

Results

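Transcriptomes of 1258 single pDCs from mouse spleen were analysed across a course of MCMV infection. The total gate held 86 cells from the uninfected mouse and 64, 57 and 64 cells from the mice infected for 33, 36 and 48 h. The LIFRlo/neg gate held 668, 168 and 85 cells, and the LIFRlo/neg YFP+ gate 10, 24 and 22 cells at those times. A last gate, LIFR+ YFP+, held 10 cells at 33 h. Cells had a median of 99278 UMIs (range 12167 to 476972) and 1077 genes. Summed over cells, the total gate had 12047637 UMIs in the uninfected mouse and 6491393, 6212415 and 7698388 at 33, 36 and 48 h. The LIFRlo/neg YFP+ sums were the smallest of the compared gates, with 1000473, 2198747 and 2916461 UMIs, against 70038069, 16094074 and 5861668 for LIFRlo/neg. Each time point is 1 mouse, so a difference between times cannot be separated from a difference between animals.

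The gates were first compared for transcripts of Ifnb1 and Lifr. Sorting itself used YFP fluorescence and surface LIFR. Median LIFR intensity was 137, 95.8 and 88.1 in total pDCs at 33, 36 and 48 h, against 185 in uninfected ones. At those times it was 29.4, 20.4 and 10.7 in LIFRlo/neg and 11.3, 8.29 and 8.24 in LIFRlo/neg YFP+ cells. Ifnb1, which encodes interferon beta and drives the reporter, had at least 1 UMI in 80.0% of LIFRlo/neg YFP+ cells at 33 h (8 of 10, exact 95% interval 44.4 to 97.5%), 62.5% at 36 h (15 of 24, 40.6 to 81.2%) and 4.55% at 48 h (1 of 22, 0.115 to 22.8%). In the LIFRlo/neg gate the shares were 19.8%, 19.6% and 4.71%, and in total pDCs 1.56%, 1.75% and 0 of 64 cells, which allows a share of up to 4.69%. No Ifnb1 UMI was found in 86 uninfected cells, which allows up to 3.49%. The share in YFP+ cells exceeded that in total pDCs in all 3 mice, by 47.9 ± 38.6 percentage points (SD, n = 3), with p = 0.25 in the two-sided exact sign-flip permutation test, the smallest p it can give. Counted over any gene of the interferon list at 1 UMI, 76.7% of uninfected cells also had a UMI, so that measure was read as background. Lifr, the gene of the receptor used for gating, had at least 10 UMIs in 10.0% of YFP+ cells at 33 h and in 0 of 24 and 0 of 22 cells later, against 31.2%, 21.1% and 21.9% of total pDCs. YFP+ minus total gave -21.4 ± 0.429 points (SD, n = 3; exact sign-flip permutation p = 0.25). Ifnb1 lies on chromosome 4 at 88522025 to 88522774 (GRCm38, minus strand, 1 exon), beside the Ifna genes at 88557673 to 88850656, and Lifr on chromosome 15 at 7090614 to 7197489.

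**Figure D1:**
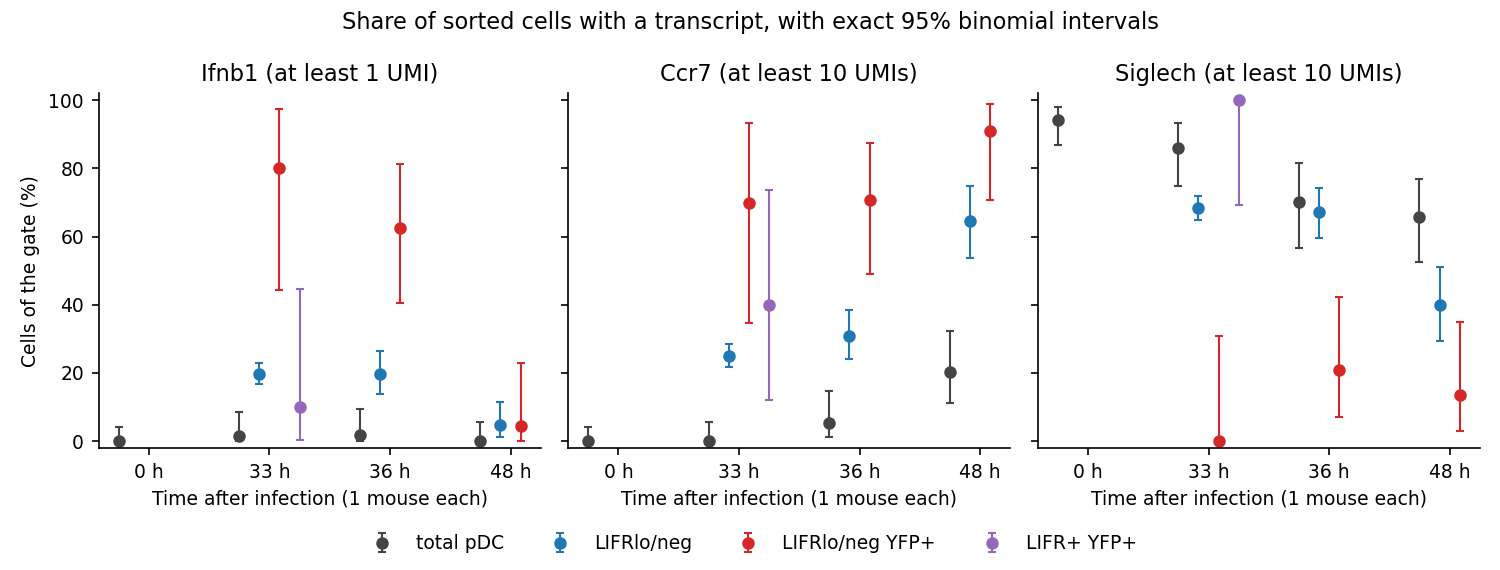
Share of cells (%) with Ifnb1 (at least 1 UMI), Ccr7 or Siglech (at least 10 UMIs) against time after infection, with points for each gate of 1 mouse per time and bars for exact 95% binomial intervals. Ifnb1 in LIFRlo/neg YFP+ cells stood at 80.0%, 62.5% and 4.55% at 33, 36 and 48 h, while Ccr7 stood at 70.0%, 70.8% and 90.9%.

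**Figure D2:**
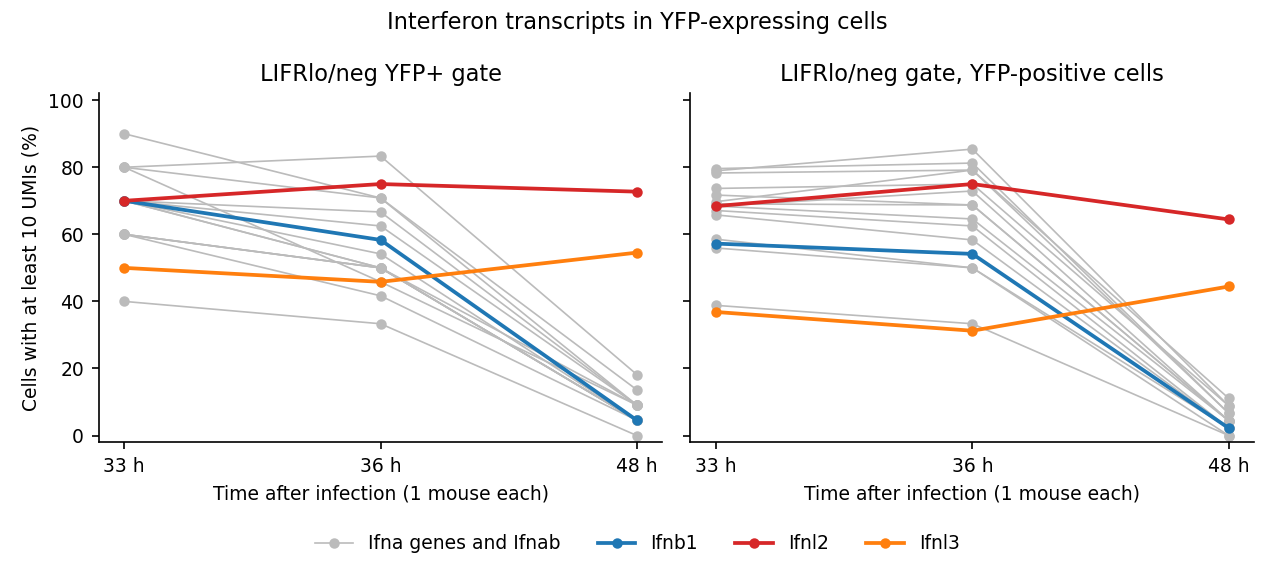
Share of cells (%) with at least 10 UMIs of each interferon gene against time after infection, 1 mouse per time, in the LIFRlo/neg YFP+ gate and in the YFP-positive cells of the LIFRlo/neg gate, with 1 line per gene. In the YFP+ gate Ifnl2 stood at 70.0%, 75.0% and 72.7% at 33, 36 and 48 h, and Ifnb1 at 70.0%, 58.3% and 4.55%.

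Infected were compared with uninfected total pDCs to ask how infection changes the whole population. Antiviral genes induced by interferon stood above the uninfected mouse in each infected one, with a median log2 ratio of 3.01, 3.07 and 2.88 over 40 interferon-stimulated genes in the 33, 36 and 48 h mice. In the fit, 32 of the 40 passed upwards and 0 downwards adjusted over the list alone, and 0 passed over all genes. That fit has 1 uninfected mouse, assumed to vary as the infected mice do, and in simulated data of this design 36 of 64 calls over all genes were false, so the counts and SEs of this comparison describe these 4 mice and are weak evidence for infection at large. Phf11d, induced by interferon, stood at 312 ± 79.7 CPM (SD, n = 3) and Oas1a, which makes the activator of the antiviral RNase L, at 231 ± 53.6 CPM, against 0.0782 CPM (1 UMI) of each in the uninfected mouse. At 10 UMIs Oas1a was found in 28.1%, 28.1% and 23.4% of infected total pDCs at 33, 36 and 48 h. Irf7, the master regulator of interferon genes, had a log2 fold change of 3.49 ± 0.44 (SE, n = 3 mice against 1). Among interferon-gamma-inducible genes 5 of 16 passed upwards adjusted over the list alone, led by the immunity-related GTPases Iigp1 (5.38 ± 0.76) and Tgtp2 (4.77 ± 0.68). The MHC class I list had 3 of 16 members passing upwards adjusted over the list alone, with H2-Q7, a nonclassical class I heavy chain gene, at 1.57 ± 0.38 (list-alone adjusted p = 0.0301). The DC maturation list had 3 of 25, with the NF-kappa-B subunit Relb (68.5 ± 26.8 CPM against 0.156 CPM) and Cd274, which encodes PD-L1 (4.59 ± 0.92). The cytokine list had 1 of 14, Il12b (7.45 ± 1.22), the p40 chain of interleukin-12, the NF-kappa-B list had 1 of 19, Relb, and the nucleic acid sensing list 1 of 16, Irf7.

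The interferon list was positive in 17 of 17 fitted values, with per-mouse medians of 1.66, 2.04 and 0.13 at 33, 36 and 48 h. In total pDCs 1 of 64, 5 of 57 and 14 of 64 cells had 10 UMIs of any of these genes. The lists that follow moved less or downwards in infected cells. No member of the cell cycle list was called, although 18 of 19 fitted changes were negative, with per-mouse medians of -1.36, -1.36 and -1.07. The transitional DC list had 11 of 14 negative values, ribosomal proteins 31 of 32 (median -0.78) and mitochondrially encoded genes 6 of 8 (-0.88). The pDC identity list had a median of 0.18 and 0 of 30 members called, with its mean at -0.05. Its members with the smallest p were Cd209d (-4.18 ± 0.86) and Ly6c2 (1.20 ± 0.28), neither of them called. Ifnb1 had 51 UMIs in the infected sums and 0 in the uninfected one (adjusted p = 0.874), and Lifr stood at 0.26 ± 0.63 (adjusted p = 0.999).

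Over 12011 genes edgeR called 0 genes in this comparison, 420 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 819. By camera at the preset correlation, 14 lists passed, with adjusted p = 2.78e-25 for interferon-stimulated genes, 1.62e-08 for MHC class I, 2.08e-07 for interferon-gamma-inducible genes, 4.06e-06 for DC maturation, 0.000193 for NF-kappa-B targets, 0.000189 for interferon genes, 0.0188 for cytokines, 0.00306 for nucleic acid sensing, 6.71e-05 for the unfolded protein response and 0.0476 for cell death, all upwards. Cell cycle (4.77e-08), ribosomal protein (0.000321), transitional DC (0.00293) and mitochondrial genes (0.0237) passed downwards. With an estimated correlation 0 lists passed: the adjusted p = 0.192 for interferon-stimulated, interferon-gamma-inducible, MHC class I, NF-kappa-B, unfolded protein response and cell cycle genes, 0.421 for interferon genes, 0.227 for DC maturation and nucleic acid sensing, 0.255 for cytokines, 0.245 for transitional DC genes, 0.498 for ribosomal and mitochondrial genes and 0.5 for cell death. At least 2 markers of the same other cell type had 10 UMIs each in 33.7% of uninfected cells. The shares in infected total pDCs were 9.38%, 7.02% and 15.6%. Single markers were more common, with Ighm, which pDCs also carry, in 93.0% and Cd68 in 59.3% of uninfected cells. Without the cells that carry any UMI of each of 2 such markers edgeR called 7 genes.

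Within the total gate, each time was set beside the uninfected mouse, as values without a test. Interferon-stimulated genes had medians of 2.98, 3.02 and 2.76 at 33, 36 and 48 h, at percentile 100 of matched random lists each time. Ifit2, which restrains translation of viral RNA, stood at 1400, 1460 and 597 CPM against 12.1 CPM, and Oasl2 at log2 ratios of 5.10, 4.67 and 4.11. Apod, a lipid carrier of the lipocalin family, stood at 4.90, 5.01 and 5.76. Secretin, Sct, was at 863 CPM at 36 h and 1669 CPM at 48 h against 0.166 CPM, from 2 UMIs in the uninfected cells. Late genes also included Ccr7, the receptor that guides dendritic cells to T cell zones, with 0 of 64, 3 of 57 and 13 of 64 cells at 10 UMIs, the chemokine gene Ccl5 (5.94 at 48 h) and the lymphotoxin gene Lta, which had 0 UMIs before infection.

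Lower values in the time course came from several groups. MHC class II genes had medians of -0.48, -0.68 and -0.81, and the C-type lectin gene Cd209d stood at -3.92 at 36 h and -5.00 at 48 h. The chemokine receptor gene Ccr2 stood at -3.50 at 36 h and had 0 UMIs in 64 cells at 48 h. Ribosomal protein genes were at -1.78, -0.78 and -0.63, with Rps26 (-3.99), Rpl35 (-3.91) and Rps19 (-3.89) among the 10 lowest genes at 33 h. The dissociation stress list, early-response genes such as Fos (-3.71 at 36 h), was at -0.01, -0.86 and -1.29. The pDC identity list stayed near 0 at 0.08, -0.00 and -0.06, while Siglech, a surface lectin of mouse pDCs chosen for description after its values were seen, was at -0.16, -0.39 and -1.02.

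YFP+ cells were compared with total pDCs of the same mice to ask what distinguishes cells that have used the Ifnb1 promoter. Interferon genes rose: 13 of 17 were called and 16 of 17 adjusted over the list alone, with none lower, and the per-mouse medians were 5.02, 5.00 and 3.12 at 33, 36 and 48 h. Ifna6 had 2534 ± 1995 CPM in YFP+ cells against 43.0 ± 35.9 CPM (SD, n = 3). Its log2 fold change was 6.25 ± 0.38 (SE, n = 3 mice; edgeR adjusted p = 0.000148). Ifna1 changed by 6.73 ± 0.52 (0.000394) and Ifna9 by 5.08 ± 0.25 (4.76e-05). These values rest in part on single cells. For Ifna6, 1 cell held 714 of 734 UMIs in YFP+ cells at 48 h. In total pDCs 1 cell held 386 of 392 at 33 h and 372 of 388 at 36 h. For Ifna1 the counts were 244 of 250, 110 of 112 and 90 of 91 in that order. Yfp itself rose by 6.83 ± 0.98 (0.0178), and Ifnb1 was at 6.90 ± 1.27 with an adjusted p of 0.0520. As the cells were sorted on the reporter, high interferon transcripts are close to the definition of the gate. Cytokine genes rose with them, 5 of 16 over all genes and 10 of 16 adjusted over the list alone, including Il12b (4.43 ± 0.38) and the macrophage inflammatory chemokine gene Ccl3 (3.62 ± 0.35).

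Genes of dendritic cell maturation were also higher in YFP+ cells. Of the DC maturation list 3 of 25 rose over all genes and 6 of 25 adjusted over the list alone, led by Ebi3, a shared subunit of interleukins 27 and 35 (3.05 ± 0.35), and Cd83, a surface marker of mature dendritic cells (4.00 ± 0.46). Of the NF-kappa-B targets 4 of 19 rose and 9 of 19 adjusted over the list alone, Cd83 and Rel (2.75 ± 0.46) among them. Ccr7, named after its values were seen, had at least 10 UMIs in 70.0%, 70.8% and 90.9% of YFP+ cells, 68.7 ± 2.75 points (SD, n = 3) above total pDCs, with p = 0.25 in the exact sign-flip permutation test. Of the interferon-stimulated genes 2 of 40 rose, Ifit1 (2.55 ± 0.32) and the RNA sensor gene Ifih1 (1.85 ± 0.29), and adjusted over the list alone 4 were higher and 3 lower. The list's median of -0.14 and mean of -0.55 were below 0, whereas camera placed it above other genes at the preset correlation (adjusted p = 0.00364) but not with an estimated one (adjusted p = 0.499 with an estimated correlation).

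pDC identity genes fell in YFP+ cells. Of 30 members 7 fell over all genes and 25 adjusted over the list alone, none was higher, and the per-mouse medians were -1.89, -1.69 and -2.13. The fitted median of the list was -2.10 beside -1.44 for all tested genes, a general shift that was -0.29 among genes with at least 10 UMIs in 10% of cells. Atp1b1, a sodium pump subunit, fell by 7.14 on the log2 scale (SE 1.19, adjusted p = 0.0339). Upb1, an enzyme of pyrimidine breakdown, fell by 3.83 ± 0.49, and Cd7 fell by 3.20 ± 0.41. The lysosomal proteases Ctsl (-1.89 ± 0.29) and Ctsb (-1.17 ± 0.18) were the 2 of 16 nucleic acid sensing genes that fell, and 4 fell adjusted over the list alone. Several genes were nearly missing from YFP+ cells. Cdh1 (E-cadherin), Rnf122, Msmo1 (a cholesterol synthesis enzyme) and Ly9 had at least 10 UMIs in 0 of 56 YFP+ cells, which allows up to 5.36%, against 22.7%, 23.2%, 14.1% and 18.4% of 185 total pDCs, and Pqlc3, Gm13919, Gm27252, Sash3 and Ccdc162 had 1 UMI each in the YFP+ sums. The YFP+ cells also had fewer genes, with medians of 927.5, 733.5 and 1227.5 per cell at 33, 36 and 48 h against 1082.5, 1009 and 1262.5, and a higher live/dead dye intensity, 7.55, 13.5 and 15.0 against 6.94, 11.8 and 9.95. Siglech had at least 10 UMIs in 0%, 20.8% and 13.6% of YFP+ cells against 85.9%, 70.2% and 65.6% of total pDCs. Lifr was at -5.85 ± 2.50 (adjusted p = 0.348).

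In all, edgeR called 68 of 9979 genes, 41 higher and 27 lower, and each moved the same way in all 3 mice. Of the lists, interferon genes (camera adjusted p = 1.17e-38) and cytokines (5.87e-16) also passed with an estimated correlation, each at an adjusted p = 0.0120. The calls of NF-kappa-B (3.4e-14), DC maturation (1.54e-11), pDC identity (1.35e-07), cell cycle (8.63e-05), interferon-gamma-inducible (0.000211), interferon-stimulated and dissociation stress genes (0.00364 each) were lost, with adjusted p = 0.073, 0.073, 0.116, 0.271, 0.116, 0.499 and 0.307 with an estimated correlation. Camera placed pDC identity genes below other genes, and interferon, interferon-stimulated and interferon-gamma-inducible genes above them. In the cell cycle list 0 of 16 members were called, and in the dissociation stress list 3 of 17 passed adjusted over the list alone. Without the 33 h mouse or without the 36 h mouse 0 genes were called, and without the 48 h mouse 24. At least 2 markers of the same other cell type had 10 UMIs each in 10.0%, 4.17% and 22.7% of YFP+ cells. Without the cells that carry any UMI of each of 2 such markers 60 genes were called.

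**Figure D3:**
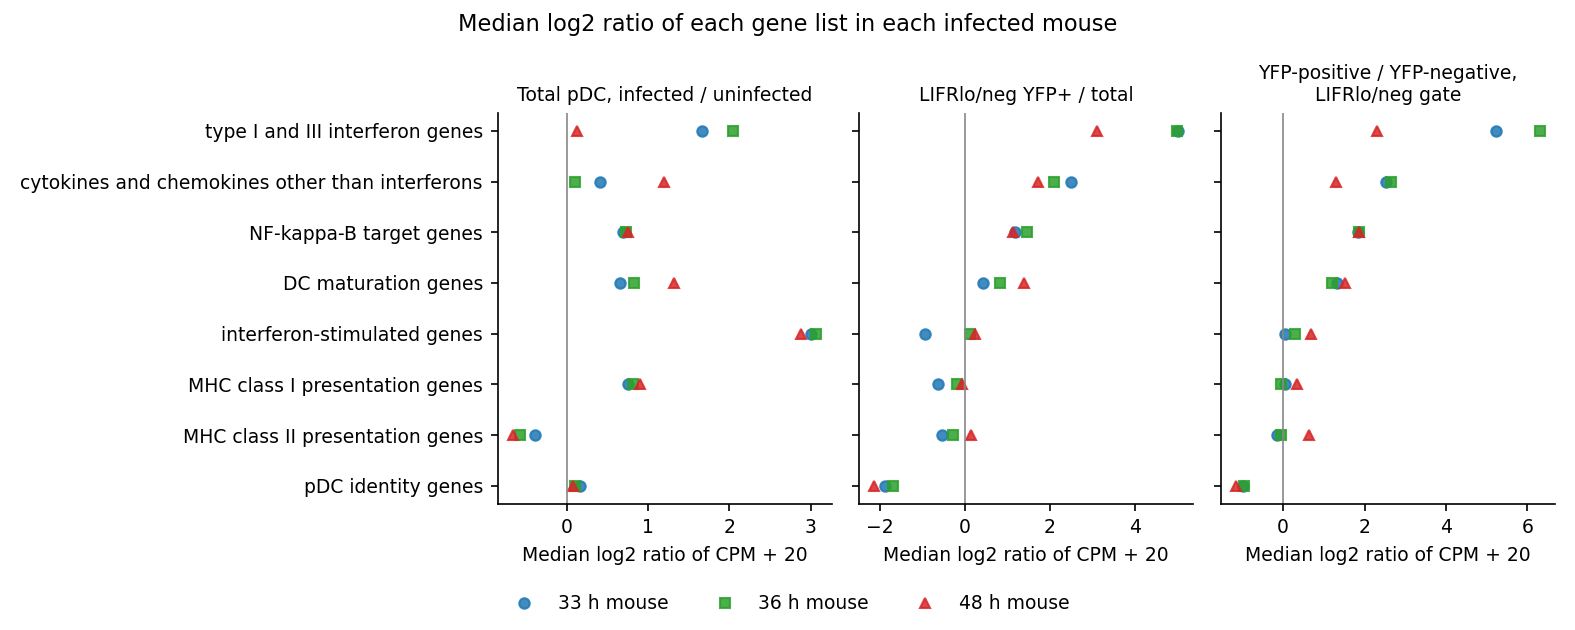
Median log2 ratio of CPM plus 20 (x axis) of 8 gene lists (y axis) in the 33, 36 and 48 h mice, 1 point per mouse, in 3 comparisons. In YFP+ against total pDCs the pDC identity medians lay at -1.89, -1.69 and -2.13 and the NF-kappa-B medians at 1.18, 1.47 and 1.14.

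The LIFRlo/neg gate, sorted without the reporter and meant by the study's design to enrich for interferon producers, was compared with total pDCs. Interferon genes rose in it: 10 of 17 were called and 16 of 17 adjusted over the list alone, with Ifna9 at 3.74 ± 0.24 (SE, n = 3 mice; adjusted p = 0.000434), Ifna6 at 4.51 ± 0.35 and Ifna1 at 4.81 ± 0.48. As in the comparison above, the Ifna6 and Ifna1 values of total pDCs at 33 and 36 h came largely from 1 cell each. Of 16 other cytokine genes 3 rose, and 12 adjusted over the list alone, including the inflammatory cytokine gene Tnf (3.35 ± 0.47), Ccl3 (2.88 ± 0.34) and Il12b (2.93 ± 0.36). In the DC maturation list 6 of 25 members and in the NF-kappa-B list 8 of 19 were higher adjusted over the list alone, and none over all genes, with Cd83 at 2.78 ± 0.43 (adjusted p = 0.0592) and Ebi3 at 1.92 ± 0.33 (0.108). Of the interferon-stimulated genes 3 of 40 were higher adjusted over the list alone, Ifit1 (1.62 ± 0.31) and Ifih1 (1.27 ± 0.29) with the smallest p. The pDC identity list had 23 of 30 values below 0 and per-mouse medians of -0.50, -0.16 and -0.82, with no member called. The live/dead dye intensity of LIFRlo/neg cells was 9.07, 14.2 and 14.3 at 33, 36 and 48 h, against 6.94, 11.8 and 9.95 in total pDCs. At least 2 markers of the same other cell type had 10 UMIs each in 6.74%, 12.5% and 20.0% of LIFRlo/neg cells. The shares in total pDCs were 9.38%, 7.02% and 15.6%. Ifnb1 was at 5.93 ± 1.25 (adjusted p = 0.316) and Lifr at -1.55 ± 1.65 (adjusted p = 1).

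All 14 genes called by edgeR among 9979 were higher in LIFRlo/neg cells, in all 3 mice. With an estimated correlation the interferon list (camera adjusted p = 6.42e-23) and the cytokine list (3.5e-14) kept their call at an adjusted p = 0.0183. DC maturation (1.59e-07), NF-kappa-B (4.79e-08), mitochondrially encoded (8.11e-05) and pDC identity genes (2.85e-10) lost theirs at adjusted p = 0.0547 each, and interferon-stimulated (0.0023), interferon-gamma-inducible (0.00504), cell cycle (0.00325) and MHC class I genes (0.0303) at 0.367, 0.367, 0.367 and 0.452 with an estimated correlation. Adjusted over the list alone, 0 members of the last-named lists other than interferon-stimulated genes passed. The 2 gates lay on different plates, and 0 genes were called without the 33 h mouse, without the 36 h mouse or without the mouse block that pairs the gates, and 18 without the 48 h mouse. With ERCC totals as the scale the median of all genes turned from 0.25 to -0.09, which is close in size to the list medians of interferon-stimulated (0.27) and MHC class I genes (0.23).

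YFP+ cells were then set against the LIFRlo/neg cells from which they were enriched. The LIFRlo/neg gate was not sorted on the reporter and itself held 22.8%, 28.6% and 52.9% YFP-positive cells at 33, 36 and 48 h. pDC genes were lower in the YFP+ gate: 1 of 30 pDC identity genes fell over all genes and 19 adjusted over the list alone, with per-mouse medians of -1.88, -1.55 and -1.38. The fitted median of the list, -1.99, lay no lower than that of all tested genes, -2.16. The median of all tested genes was -0.35 among genes with at least 10 UMIs in 10% of cells and -1.17 without the 33 h mouse. Ly6d, a surface marker of pDCs and their lymphoid precursors, fell by 1.84 ± 0.20 on the log2 scale (SE, n = 3 mice; adjusted p = 0.0293), Rnase6, a secreted ribonuclease, fell by 2.13 ± 0.23 (0.0293), and Pqlc3 had 1 UMI in the YFP+ sums against 12632. LIFRlo/neg cells had medians of 1018, 1105 and 1312 genes at 33, 36 and 48 h, above those of YFP+ cells in each mouse. Interferon genes were higher, 12 of 17 adjusted over the list alone and 0 over all genes, with Ifna6 at 1.74 ± 0.31, Ifna9 at 1.33 ± 0.22 and Ifnb1 at 0.97 ± 1.05 (adjusted p = 0.715). Il12b (1.51 ± 0.34) was the 1 cytokine gene of 16 higher adjusted over the list alone. Lifr was at -4.30 ± 2.58 (adjusted p = 0.441), and the interferon-stimulated gene Ly6a at -1.55 ± 0.27 was 1 of 2 lower adjusted over the list alone.

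Of 9979 genes, edgeR called 0 higher and 3 lower, with 1476 at an unadjusted p under 0.05, DESeq2 calling 1319 and limma-voom 527 in both directions. The interferon list passed camera (8.31e-76) and kept its call with an estimated correlation, adjusted p = 0.00438. Calls of DC maturation (1.83e-06), cytokine (4.34e-05), NF-kappa-B (1.34e-09), pDC identity (0.000225), interferon-stimulated (0.00641), interferon-gamma-inducible (0.0114) and dissociation stress genes (0.00801) were lost, at adjusted p = 0.133, 0.133, 0.133, 0.200, 0.450, 0.273 and 0.393 with an estimated correlation. Camera placed the upward lists above other genes, yet the medians of interferon-stimulated (-0.42), interferon-gamma-inducible (-0.24) and dissociation stress genes (-0.25) were negative, as were the means of DC maturation (-0.47), cytokine (-1.06) and NF-kappa-B genes (-0.17). Of the MHC class I and nucleic acid sensing lists, 2 of 16 and 3 of 16 members were lower adjusted over the list alone, among them H2-K1 (-0.69 ± 0.17) and Ctsb (-0.92 ± 0.18). The 3 calls were lost with RLE size factors, summed UMIs, ERCC totals and on leaving out any 1 mouse, and 10 genes were called without the mouse block.

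Within the LIFRlo/neg gate, cells with YFP fluorescence were compared with cells without it. Interferon genes rose, 11 of 17 over all genes and 17 of 17 adjusted over the list alone, with Ifnb1 at 7.55 ± 0.51 (SE, n = 3 mice; adjusted p = 0.0116), Yfp at 7.99 ± 0.37 and Ifna5 at 5.05 ± 0.27, which is close to definitional for a reporter of Ifnb1. With the pseudocount of 20 CPM, log2 ratios at 33, 36 and 48 h were 4.54, 4.40 and 1.28 for Ifnb1, 6.04, 6.06 and 1.29 for Yfp and 5.22, 6.30 and 2.31 for the median of the list. The pseudocount holds down the ratio where few UMIs are present. Ifnb1 stood at 427, 414 and 29.4 CPM in YFP-positive against 2.08, 2.55 and 0.436 CPM in YFP-negative cells, so its abundance differed between mice. At 48 h 1 of 45 YFP-positive cells had 10 UMIs of Ifnb1, and that cell held 92 of the 93 UMIs. The interferon lambda genes Ifnl3 (7.59 ± 0.55) and Ifnl2 (5.82 ± 0.57) rose too. Maturation genes rose with them, 4 of 24 over all genes and 14 adjusted over the list alone, led by Ebi3 (3.97 ± 0.19) and Ccr7 (3.77 ± 0.34). Of 19 NF-kappa-B targets 7 rose and 14 adjusted over the list alone, with the survival gene Bcl2a1d at 5.02 ± 0.31 and Nfkbiz at 2.97 ± 0.24. The chemokine gene Ccl5 (5.71 ± 0.38) was the 1 called cytokine of 16, and 12 passed adjusted over the list alone.

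pDC identity genes were lower in the YFP-positive cells, with 1 of 30 called, 17 lower adjusted over the list alone and per-mouse medians of -0.98, -0.96 and -1.16. Smim5 fell by 3.56 ± 0.43 and Lefty1, a TGF-beta family antagonist, fell by 2.74 ± 0.34 on the log2 scale, and Ccr9, a gut-homing receptor gene of pDCs, was at -1.49 ± 0.22 (adjusted p = 0.0734). The live/dead dye intensity of YFP-positive cells was 11.3, 15.9 and 16.4 at 33, 36 and 48 h against 8.39, 13.0 and 10.6, and their median number of genes 894.5, 958.5 and 1331 against 1059, 1156.5 and 1275. Of 40 interferon-stimulated genes 2 rose, Ifit1 (2.45 ± 0.22) and Ifit3 (3.01 ± 0.35), and 12 adjusted over the list alone. Ifitm1, an antiviral membrane protein gene, was called too, at 164 ± 187 CPM (SD, n = 3) in YFP-positive cells and 7 UMIs in the YFP-negative sums. Its fitted change of 9.22 ± 1.03 depends on the prior count. The per-mouse log2 ratios were 1.56, 2.19 and 4.32 at 33, 36 and 48 h. Of the cell death list 4 of 12 were higher adjusted over the list alone, including the pro-apoptotic Bcl2l11 (5.92 ± 0.91) and the anti-apoptotic Bcl2l1 (6.23 ± 1.06), and of the dissociation stress list 3 of 17, including Junb (1.98 ± 0.32). Lifr was at -2.21 ± 2.83 (adjusted p = 0.902).

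In this comparison edgeR called 42 of 9215 genes, 40 higher and 2 lower, each in the same direction in all 3 mice. Camera passed interferon (3.86e-37), NF-kappa-B (3.72e-18), DC maturation (1.51e-17), cytokine (6.17e-15), pDC identity (1.44e-14), interferon-stimulated (2.24e-05), interferon-gamma-inducible (0.000531), mitochondrially encoded (0.00122), dissociation stress (0.00575) and cell death genes (0.00751). With an estimated correlation none did, at adjusted p = 0.206, 0.0979, 0.0979, 0.0979, 0.102, 0.483, 0.404, 0.491, 0.411 and 0.427. Without the mouse block 14 genes were called, without the 33 h or the 36 h mouse 0, and without the 48 h mouse 123.

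At 33 h, LIFR+ YFP+ cells were set beside LIFRlo/neg YFP+ cells of the same mouse, 10 cells each and with no test. The 2 gates also differed in the reporter. Median YFP intensity was 128 in LIFR+ YFP+ against 580 in LIFRlo/neg YFP+ cells. Yfp had at least 10 UMIs in 1 of 10 against 8 of 10 cells, and any interferon gene in 1 of 10 against 9 of 10. pDC transcripts were higher in LIFR+ YFP+ cells. Siglech had at least 10 UMIs in 10 of 10 cells (2315 CPM, exact 95% Poisson interval 2232 to 2400) against 0 of 10, and Smim5 was at 1247 CPM against 1.00 CPM. The pDC identity list had a median log2 ratio of 1.58, at percentile 99.99 of random lists, and MHC class II genes 0.83, at percentile 99.26. The cDC-associated list was higher too, with a median of 2.17 at percentile 97.66 and 10 of 13 members up. Cytokine transcripts were lower in them. Ifnl2 was at 8.59 CPM against 6413 CPM and Il12b at 1.56 CPM against 4458 CPM, while Il27 and Lta had 0 UMIs against 2836 and 2222 CPM. The medians of the interferon (-3.13), cytokine (-3.00), NF-kappa-B (-2.69) and DC maturation lists (-2.64) lay below all random lists, and the interferon-stimulated list stood at 0.02. Ifnb1 had at least 10 UMIs in 1 of 10 against 7 of 10 cells, and Lifr was at 161 against 160 CPM.

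The remaining lists were mostly not called. MHC class II genes had adjusted p = 0.127, 0.687, 0.0799, 0.719 and 0.645 by camera for infection, YFP+ against total, LIFRlo/neg against total, YFP+ against LIFRlo/neg and YFP-positive against YFP-negative cells. In that order the values were 0.115, 0.841, 0.792, 0.0880 and 0.743 for cDC-associated genes and 0.401, 0.252, 0.893, 0.160 and 0.238 for glycolysis. In the 4 comparisons of gates and reporter, ribosomal protein genes had 0.606, 0.171, 0.674 and 0.743 and the unfolded protein response 0.104, 0.171, 0.0684 and 0.464, with no member called over all genes in any. Adjusted over the list alone, 2 of 21 unfolded protein response genes were higher and 1 lower in YFP+ than in total pDCs, and 2 were lower in YFP+ than in LIFRlo/neg cells. The cDC-associated list had 4 of 18 members lower in YFP+ than in total pDCs adjusted over the list alone, with Clec10a at -3.37 ± 0.66, 4 of 18 lower in YFP+ than in LIFRlo/neg cells, and 1 higher and 2 lower of 17 in YFP-positive than in YFP-negative cells. Among markers of other cell types the camera test gave, for infection, adjusted p = 0.419 for B cells, 0.419 for plasma cells, 0.103 for T cells and 0.246 for monocytes and macrophages. NK cell, neutrophil and erythroid lists had at most 3 tested members and none called. The most abundant such transcript, Ighm, which pDCs also carry, was at 1710 CPM in uninfected cells and 1500, 1605 and 1474 CPM in total pDCs at 33, 36 and 48 h.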

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

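The tests of depth, of fluorescence unrelated to interferon, of lost interferon transcripts, of UMIs taken up by interferon transcripts and of carry-over were chosen only after the results they bear on were seen.

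The medians of several gene lists lay on opposite sides of 0 in different mice under the same gate comparison. These differences between times were not tested, as each time is 1 mouse. The gates set beside YFP+ cells also held changing shares of YFP-positive cells. By fluorescence these were 22.8%, 28.6% and 52.9% of LIFRlo/neg cells at 33, 36 and 48 h, and 3.13%, 1.75% and 20.3% of total pDCs. The contrast between gates is therefore not the same at each time. In YFP+ against total pDCs, interferon-stimulated genes were at -0.93, 0.11 and 0.23 at 33, 36 and 48 h, and interferon-gamma-inducible genes at -0.30, 0.02 and 0.94. In LIFRlo/neg against total pDCs, interferon-stimulated genes were at -0.035, 0.26 and 0.70 and MHC class I genes at -0.088, 0.09 and 0.53. In YFP+ against LIFRlo/neg cells, interferon-gamma-inducible genes were at -0.38, -0.67 and 0.11, DC maturation genes at 0.58, 0.24 and -0.01, NF-kappa-B targets at 0.63, 0.51 and -0.07, other cytokines at 0.091, 0.24 and -0.08 and dissociation stress genes at 0.19, -0.57 and 0.42.

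Among the index-sort channels other than YFP and LIFR, BST2, CD11c and the live/dead dye were above the uninfected level in total pDCs of all 3 infected mice, whereas CD11b and the lineage cocktail were below it at 36 and 48 h. BST2, a surface protein of pDCs that interferon raises on other cells, had a median intensity of 55.2 in uninfected cells and 113, 132 and 136 at 33, 36 and 48 h. CD11c stood at 30.0 against 56.2, 60.6 and 54.5, and the live/dead dye at 3.23 against 6.94, 11.8 and 9.95. Over the 8 plates of LIFRlo/neg cells at 33 h, 14 measures were checked for a plate far from the rest, and 0 met the limit.

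Cells sorted as YFP+ at 48 h carried transcripts of fewer interferon genes than at 33 and 36 h. Lower depth is argued against, as these cells were the deepest of the gate, with a median UMI count 1.26 times that at 33 h. A loss of all interferon transcripts is argued against, as is fluorescence in cells without any. At 48 h 86.4% of these cells (19 of 22, lower bound 65.1%) had 10 UMIs of an interferon gene. That share was 90.0% and 95.8% at 33 and 36 h, and its upper bound in total pDCs at 48 h was 34.0%. It rested largely on interferon lambda, with Ifnl2 in 16 and Ifnl3 in 12 of the 22 cells. Ifnb1 and Yfp reached 10 UMIs in 1 of 22 cells each. The share therefore does not bear on whether the fluorescence came from the Ifnb1 reporter. A candidate explanation is that type I interferon transcripts were lost before the cells matured while the fluorescent protein stayed. YFP-positive LIFRlo/neg cells without 3 interferon genes at 10 UMIs had Ccr7 less often than those with them at 33 h (18 of 27 against 95 of 125 cells, -9.33 points). They had it more often at 36 h (7 of 7 against 26 of 41, 36.6 points), and at 48 h the counts were 36 of 38 against 6 of 7. Some of these groups are small, and the 3 genes can include interferon lambda genes, so the explanation stays open. Fluorescence of maturing cells from outside the reporter and a difference between the 48 h mouse and the others were not tested and stay open too.

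pDC identity transcripts were lower in YFP+ than in total pDCs. Interferon transcripts taking up UMIs are argued against, because the smallest per-mouse median of the list was -1.69, while the UMIs left after interferon transcripts would give -0.10. Conventional DCs within the YFP+ gate may contribute: Siglech was at least as frequent as in total pDCs in 0 mice, yet the cDC-associated list had a median of -1.47 beside -1.44 for all genes and was not raised, and cells that mature can lose both sets of markers. The cells were sorted as pDCs, and their median BST2 intensity of 178, 159 and 179 at 33, 36 and 48 h, against 113, 132 and 136 in total pDCs, goes against an influx of BST2-low cells, although interferon raises BST2 on other cells too. With that, conventional DCs and a loss of identity genes by pDCs themselves cannot be told apart with these values.

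Interferon UMIs were found in 76.7% of the 86 uninfected cells. Low-level carry-over between libraries is consistent with their size, since the highest count per gene in an uninfected cell was 9 UMIs and 0 cells reached 10. No biological explanation was tested.

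The gate comparisons were repeated in the same blocked fits, with the sums of a gate outside the comparison kept in place, over all 10 splits of the 6 compared sums into groups of 3. In each, 1 split, the real one, gave as many genes. The real counts were 68 for YFP+ against total, 14 for LIFRlo/neg against total, 3 for YFP+ against LIFRlo/neg and 42 for YFP-positive against YFP-negative cells, and the highest of the other splits was 0 in each, as it was among the 3 of them that, like the real split, part the sums of every mouse. With 10 splits the share cannot fall under 0.05. In the other splits the difference between the real gates also enters the residual spread. Few calls are likely there whether or not the real calls hold, so no conclusion is drawn from the 0 counts.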

How the results depend on the processing

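Alternatives chosen after the data were seen were counts of cells with 10 UMIs, collision correction, ERCC totals, the filter on 10% of cells, the comparison by fluorescence, the exclusion of cells with 10 UMIs of 2 markers, the 10 UMI, 3-gene and Yfp shares, the thinned shares over several interferon genes and the shares without 1 mouse. Counts of called genes are given below for infection, YFP+ against total, LIFRlo/neg against total, YFP+ against LIFRlo/neg and YFP-positive against YFP-negative cells, whose main counts were 0, 68, 14, 3 and 42, where they moved by over 1.5 times. DESeq2 called 819, 1893, 204, 1319 and 854, and no filter left 28, 108, 33, 56 and 110. Mean log CPM per cell with limma gave 793, 268, 0, 13 and 246, and counts of cells with 10 UMIs gave 115, 154, 65, 6 and 577. limma-voom gave 609, 37, 527 and 758 for the last 4. The 10% filter gave 8, 0 and 202 for the last 3. RLE size factors, summed UMIs alone and ERCC totals gave 0 for YFP+ against LIFRlo/neg. Without cells with any UMI of 2 markers of the same other type 7 genes were called for infection and 1 for YFP+ against LIFRlo/neg. Without cells with 10 UMIs of 2 markers the count was also 1 for YFP+ against LIFRlo/neg. Fits on the 6 sums of the 2 gates alone gave 8 for LIFRlo/neg against total and 61 for YFP+ against LIFRlo/neg. The cause of these shifts was not tested. Leaving out 1 mouse gave 0 to 24, 0 to 18, 0 to 0 and 0 to 123 for the last 4 and 0 to 0 for infection, and the cause was not tested. Without the mouse block that pairs the gates the counts were 46, 0, 10 and 14. The main counts of lists passing were 14, 9, 10, 8 and 10. An estimated correlation left 0, 2, 2, 1 and 0, fry gave 9 for infection, 6 for LIFRlo/neg against total, 4 for YFP+ against LIFRlo/neg and 6 by fluorescence, and leaving out 1 mouse gave 7 to 16 for LIFRlo/neg against total.

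The excess of Ifnb1-positive cells in YFP+ over total pDCs, 47.9 points, became 5.34 points over any interferon gene at 1 UMI, where background is counted, and ranged from 32.6 to 69.6 points without 1 mouse. The other alternatives, 35.7 (Ifnb1, thinned) to 80.0 points (any interferon gene at 10 UMIs), stayed within 1 SD. Among time course values in the total gate, the mean over times of the median of interferon-stimulated genes, 2.92, became 3.46 with a pseudocount of 5 CPM, and that of interferon genes in LIFR+ YFP+ cells, -3.13, became -3.24. Among named genes 5 values changed sign, none of a called gene: Lifr for infection (-0.19 without cells with markers of other types, -0.17 without cells with 10 UMIs of 2 markers and -0.17 to 0.45 on leaving out 1 mouse), Lifr, YFP-positive against YFP-negative LIFRlo/neg cells (-5.14 to 0.23 on leaving out 1 mouse) and H2-Aa in YFP+ against LIFRlo/neg cells (0.035 as counts of cells). For YFP+ against total, over 34 genes, 468 values kept direction and side of the threshold, 121 lost the call and 17 gained one. The block changed no other call by over 1.5 times. Shares of annotated classes were not run, as no annotation was used here. Few cells limit the YFP+ gate, with 56, and the LIFR+ YFP+ gate, with 10.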

Other observations

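Interferon lambda and type I interferon genes were found at different shares among YFP-expressing cells of the 3 times. In the YFP+ gate most cells fell in the interferon-producing-like cluster at 33 h and in the mature-DC-like cluster at 48 h, so the times may compare different mixtures of cells. The first cluster was itself led by interferon genes, so that split is in part the interferon transcripts counted again. Ifnl2 and Ifnl3, which encode interferon lambda and lie on chromosome 7 at 28508836 to 28510455 and 28522836 to 28524322, had at least 10 UMIs in 72.7% (16 of 22) and 54.5% (12 of 22) of YFP+ cells at 48 h, when Ifnb1 had 10 UMIs in 4.55% and the Ifna genes and Ifnab in 0% to 18.2%. At 33 h and 36 h Ifnl2 was found in 70.0% and 75.0% and Ifnl3 in 50.0% and 45.8% of YFP+ cells. In CPM, Ifnl2 stood at 6413, 6703 and 3581 and Ifnl3 at 4182, 3330 and 2776. YFP-positive cells of the LIFRlo/neg gate, other cells of the same mice on other plates, had Ifnl2 in 68.4%, 75.0% and 64.4% and Ifnl3 in 36.8%, 31.2% and 44.4%. Among total pDCs at 48 h, Ifnl2 was found in 12.5% (8 of 64) and Ifnl3 in 6.25% (4 of 64), and neither in 86 uninfected cells. Single cells reached 1024 UMIs of Ifnl2, the most that a UMI of 5 bases can count, so its CPM are lower limits in such cells. The 48 h values come from 1 mouse, these genes were chosen after their values were seen, and no test was run.

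Ccr7 and Siglech went opposite ways with the reporter inside the LIFRlo/neg gate. Ccr7 had at least 10 UMIs in 74.3%, 68.8% and 93.3% of YFP-positive cells at 33, 36 and 48 h against 8.49%, 12.5% and 24.2% of YFP-negative cells, and Siglech in 42.1%, 43.8% and 8.89% against 77.5%, 78.8% and 81.8%. YFP-negative cells in this gate still had 3 interferon genes with at least 10 UMIs in 10.2%, 5.77% and 3.03% of cells. Over the 8 plates of 33 h LIFRlo/neg cells, the share with Ccr7 was 25.0 ± 5.96% and that with Ifnb1 19.7 ± 6.49% (SD over plates of 1 mouse).

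Clustering gave 5 clusters. An interferon-producing-like cluster of 198 cells was led by Ifna6 and Ifnab, a pDC-like cluster of 876 cells by Smim5, Lefty1 and Cox6a2, and a mature-DC-like cluster of 152 cells by Fscn1, Ebi3 and Ccr7 together with the immunoglobulin gene Ighg2b. A cluster of 19 cells led by Ms4a6b and Fcgr1, and one of 13 cells led by the plasma cell genes Jchain and Igha, stayed unnamed. The 13 cells all lay in the LIFRlo/neg gate, 10 at 36 h and 3 at 48 h, and 46.2% of them had 10 UMIs of the B cell marker Cd79a.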
